A study of Homo sapiens with 16 samples.

How the data were processed

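RNA of HK2 cells treated with CPP was measured on 16 single-colour Agilent expression arrays, 4 at each of 0, 3, 6 and 24 h. Spot intensity values were made from the scanned images with Agilent Feature Extraction 11.0.1.1 under the protocol GE1_1100_Jul11, per the file headers. Local background was subtracted and trends across the array were removed within each array, per the file headers. The deposited scanner files hold this processed signal for each spot, with the median signal, the local background median and flags for outlier, saturated and well above background spots. The deposited value table holds 1 intensity per probe and sample. Set against the scanner files, it was found to be the unlogged mean of the processed signals of a probe's replicate spots, with control spots removed and no scaling between arrays. No gene was centred, and the values are signals of 1 channel, so no ratio direction applies. Which software step wrote the value table is not given in the sources used here.

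Samples were grouped by time and numbered as replicates 1 to 4 from their labels. Each column of the value table carries a sample's name and equalled the signals of exactly 1 scanner file on all 58201 probes (relative tolerance 0.0001). For 4 of the 16 samples this was the file attached to the same sample, and for 12 it was a file attached to another. Each array was given to the sample whose value-table column holds its values. The plan fixed before the data were examined took each scanner file's sample from its attachment and used the value table as an alternative. The order was changed after the disagreement was found and after gene counts under both orders had been seen. The attachment order is kept as an alternative for every count, gene and list. The plan also stated that each time lay on 1 slide and that slide could not be a block. That holds for the attachment order, whereas by the value table each slide held 2 arrays of each time. Replicates 1 and 2 were on slide 1 and replicates 3 and 4 on slide 2. Slide as a block and fits within each slide were therefore added after seeing the data.

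Control spots were left out, as were 1429 spots marked as outliers over all arrays and 9 probes that had only such spots on at least 1 array. Replicate spots of a probe were averaged. The values are log2 of the processed signal minus the array's 75th percentile over non-control probes. Between 26291 and 28649 probes (45.2% to 49.2%) were well above background on an array and 0 were saturated. The number of arrays limits the precision of a mean. The medians of the value-table columns, in signal units, were 8.86, 9.72, 9.44 and 11.3 for replicates 1 to 4 at 0 h and 9.54, 9.19, 10.2 and 11.1 at 3 h. They were 9.44, 9.48, 11.7 and 12.9 at 6 h and 9.59, 9.47, 11.2 and 10.4 at 24 h. Arrays of 1 time correlated across the tested genes with r between 0.997 and 0.998, and no pair held identical values.

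The scanner files name no genes. Of the 33080 probes with a RefSeq accession, 31104 (94.0%) were named through the RefSeq table of GRCh38.p14, without accession versions. Of all 58201 probes, 27097 stayed unnamed and outside the gene tests. These gave 22439 genes, 18216 of them protein-coding, and 6754 had more than 1 probe. A gene was represented by its probe with the highest mean over the 16 arrays, and where the median over its probes changed the call or direction of a gene named in the results, this is stated. The grid of the array refers to hg19, per the file headers, while the table refers to another build, so no coordinates are given.

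Genes whose probe was well above background on all 4 arrays of at least 1 time were tested, 14679 in all. limma (3.58.1) was fitted to all 16 arrays with 1 mean per time, 12 residual and 2.18 prior degrees of freedom. Contrasts were tested two-sided with eBayes and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p below 0.05. The contrasts were 3, 6 and 24 h against 0 h, 24 h against 6 h and 6 h against 3 h, with a moderated F-test over the times against 0 h. Genes changed at least 2-fold were counted among those called. Lists of genes, 32 in all and 4 of them markers of other cell types, were fixed before the data were examined. Each list was tested by limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation as the alternative. A list needed 3 tested members. Overlaps of early and late calls were tested by Fisher's exact test, two-sided, in each direction. For a probe well above background in only 1 of the groups, a fold is a lower bound.

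The rule for the genes named was also fixed before the data were examined. For 3, 6 and 24 h against 0 h it took the 8 largest rises and 8 largest falls among called genes whose groups did not overlap over 4 replicates and whose probe was well above background and not saturated on all 8 arrays. Placeholder names were left out. It added up to 3 genes per direction that were well above background on all 4 arrays of one group and none of the other, ranked by their lower bound. For each list that passed it took up to 4 called members with the largest change in the direction of the test, and for each other list up to 2. For 24 h against 6 h it took the 4 largest rises and 4 largest falls by the same criteria. A gene named outside this rule is said to be chosen after its values were seen. Some single-gene results that the rule selects are not reported here, but they stay in the counts of gene results and in the lists.

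Alternatives planned before the data were examined were quantile normalization, scaling by the median, normexp background correction (offset 50) and the value table without scaling. Others were no filter on dim probes, a filter on all 16 arrays, the median over a gene's probes, an intensity trend with robust spread and fits of only the groups compared. The replicate number as a block, leaving out each array in turn, a test against a fold of 1.2, an estimated correlation and limma's fry complete the plan. The files used here hold no mean signal, so normexp used the median, and its offset shrinks changes of dim probes. The attachment order, slide block and within-slide fits were added after seeing the data. List results for 24 h against 6 h and 6 h against 3 h were also taken through the alternatives.

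Whether replicate numbers pair the samples was checked on deviations from the group means. In all 24 pairs of arrays with the same number these correlated with r between 0.153 and 0.344 (median 0.252), above the 0.1 set for pairing. Arrays of different number on the same slide had a median of 0.241 and those on different slides -0.258, and 10 of 16 arrays correlated best with their own number. The pairing comes from the replicate numbers in the labels, and the numbers follow the slides.

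The fit was tested on 14679 genes simulated independently from real means and spreads for 3 h against 0 h. Of 50 changed at each fold it recovered 33 at 1.2, 43 at 1.5, 48 at 2 and 50 at 3, with 4 false calls among 178. A lysosome list shifted by 0.3 passed camera and 0 of the other 31 did, which leaves correlated genes untested. The analysis used R 4.3.3, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9. Untreated cells at later times were not analysed, and unnamed probes were only counted.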

Results

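Gene expression was measured in HK2 cells, an immortalised line of human kidney proximal tubule epithelium, before and during treatment with CPP, an abbreviation that the labels do not expand. RNA was taken at 0, 3, 6 and 24 h and hybridised to 16 Agilent single-colour arrays, 4 per time. Each array carried 58201 non-control probes, of which between 26291 and 28649 were well above background, and no probe was saturated. A gene was tested where its brightest probe was well above background on all 4 arrays of at least 1 time, which left 14679 genes. Changes are given as log2 differences between group means, with the standard error of the limma fit and n = 4 arrays per time. The labels name replicates but not separate cultures, so the p-values measure only the spread between these samples, which may be technical. Largest rises and falls are given among called genes whose groups did not overlap and whose probe was well above background on all 8 arrays. The labels of these 16 samples name no untreated cells at 3, 6 or 24 h, so treatment and time in culture were not separated.

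The deposited records disagree on which array belongs to which sample. Each column of the deposited value table equalled the signals of exactly 1 scanner file, but for 12 of the 16 samples that file was attached to another sample. The design fixed before the data were examined took each scanner file's sample from its attachment. Arrays were instead grouped here by the value table, a change made after counts under both orders had been seen, and all values below depend on it. With arrays grouped by file attachment, limma called 2 genes at 3 h, 133 at 6 h and 185 at 24 h against 0 h. It called 0 at 24 h against 6 h and 189 at 6 h against 3 h. Under that order 0 h and 3 h lay on slide 1 and 6 h and 24 h on slide 2. Slide and time therefore cannot be told apart in the comparisons with 133, 185 and 189 calls. At an unadjusted p below 0.05 the attachment order gave 268, 1027, 1130, 265 and 1216 genes. Of 223 results for single genes, 103 had the opposite sign under the attachment order. Of 50 results for gene lists, camera gave 23 the opposite direction, and the mean had the opposite sign in 26. None of these genes or lists passed the limma or camera test there. Ranges of adjusted p given below for a result's alternatives leave the attachment order out. Under the value-table order each time had 2 arrays on each of 2 slides, and the column of the slide followed time, so column position and time were not separated by the design. The first principal component held 35.5% of the variance and ordered the arrays by time, and the next held 16.1% and parted the slides.

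**Figure D1:**
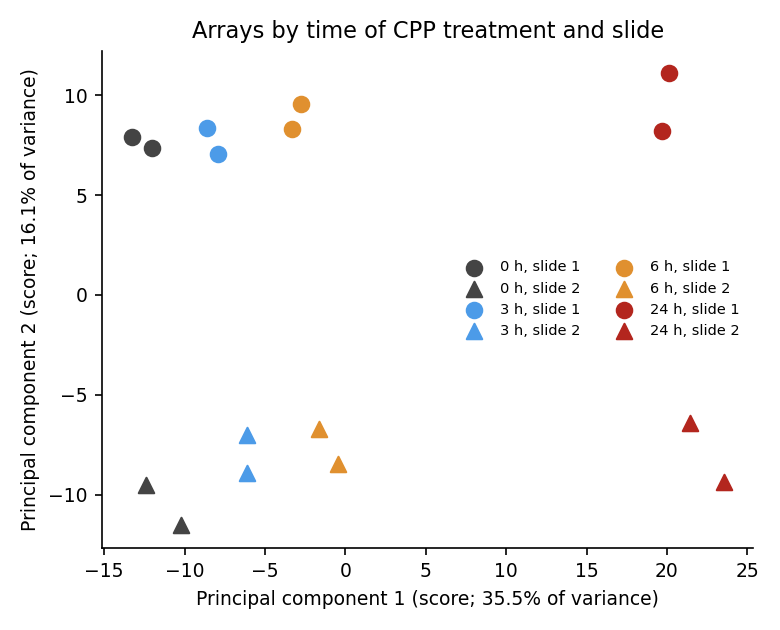
Scores of the 16 arrays on principal components 1 (35.5% of variance) and 2 (16.1%), coloured by time of CPP treatment, with circles for slide 1 and triangles for slide 2 (arrays grouped by the value table). Component 1 runs from the 0 h arrays on the left to the 24 h arrays on the right, and component 2 parts the slides.

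**Figure D2:**
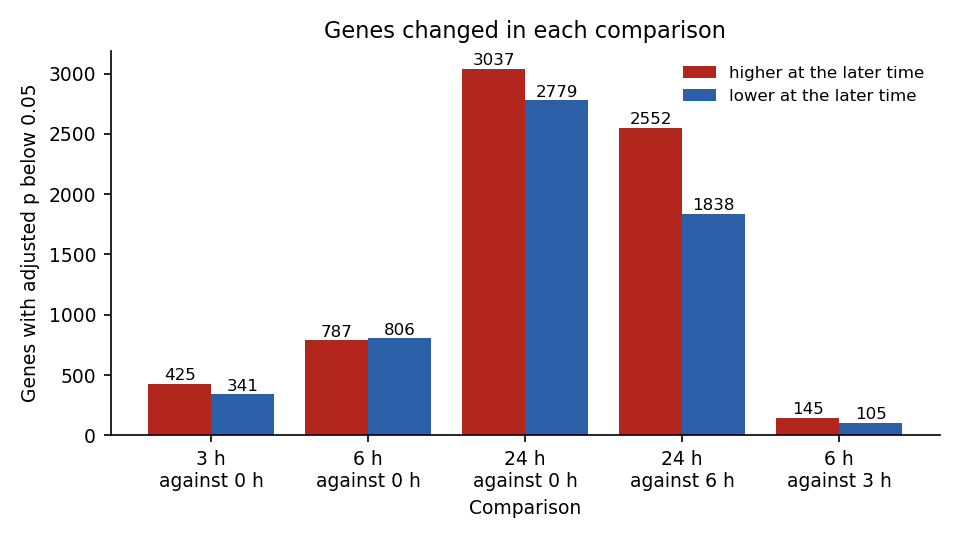
Number of genes with adjusted p below 0.05 in each comparison (limma, arrays grouped by the value table), higher at the later time in red and lower in blue. At 24 h against 0 h 3037 genes were higher and 2779 lower, against 425 and 341 at 3 h.

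At 3 h against 0 h, the comparison that asks for the earliest measured response, the clearest change was a rise of immediate early genes. FOS, a subunit of the AP-1 transcription factor, rose by 2.34 ± 0.04 on the log2 scale (adjusted p = 9.9e-14), and its relative FOSB by 1.47 ± 0.08. The nuclear receptor gene NR4A3 rose by 1.54 ± 0.12 and the zinc finger transcription factor gene EGR1 by 1.08 ± 0.06. NR4A3 missed the threshold within slide 1 alone (1.36, adjusted p = 0.089, the highest over its alternatives). DUSP5 and SPRY4, which encode feedback inhibitors of ERK signalling, rose by 1.03 ± 0.06 and 0.78 ± 0.07. SPRY4 missed the threshold as the median of its probes (0.40, adjusted p = 0.18, range over its alternatives 2.0e-06 to 0.18). Of 24 immediate early and MAPK feedback genes tested, 21 rose and 0 fell (23 and 0 when adjusted over the list alone). The list moved up against the other genes (camera adjusted p = 3.9e-41, and adjusted p = 4.8e-05 with an estimated correlation). Its mean change was 0.54, with means of 0.54 and 0.54 within slides 1 and 2.

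Some ATF4 targets and hypoxia genes also rose at 3 h. Of 22 targets of ATF4, the transcription factor of the integrated stress response, 5 rose and 0 fell (10 and 1 when adjusted over the list alone). The camera test gave them adjusted p = 9.2e-07, and adjusted p = 0.0075 with an estimated correlation. They included ATF3 (1.25 ± 0.05, with 0.28 to 1.33 for its other probes), DDIT4, an inhibitor of mTOR signalling (0.71 ± 0.02), PPP1R15A (0.38 ± 0.05) and CHAC1 (0.31 ± 0.04). Of 20 hypoxia and glycolysis genes, 5 rose and 0 fell (9 and 0 when adjusted over the list alone). Camera gave them adjusted p = 2.5e-07, and adjusted p = 0.043 with an estimated correlation. Among them were ANGPTL4, an inhibitor of lipoprotein lipase (0.45 ± 0.07), the hexokinase gene HK2 (0.39 ± 0.05), PFKFB4 (0.36 ± 0.04) and EGLN3 (0.31 ± 0.07). EGLN3 missed the threshold without 3 h replicate 1, 2 or 3 (adjusted p = 0.0624, 0.0629 and 0.0552, range over its alternatives 0.0163 to 0.896). Genes from lists that did not pass included the cytokine genes IL11 (0.76 ± 0.04) and CXCL8 (0.39 ± 0.06), GDF15 (0.72 ± 0.05), SOX9 (0.54 ± 0.06) and IFIT1 (0.52 ± 0.07). Others were F3, the gene of tissue factor (0.45 ± 0.04), PLK3 (0.40 ± 0.04), IFIT2 (0.40 ± 0.05), PAX8 (0.30 ± 0.04) and IL18 (0.19 ± 0.03).

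The largest falls at 3 h were in ID2 (-0.92 ± 0.03), SMAD9 (-0.87 ± 0.08), ID3 (-0.82 ± 0.05), VXN (-0.65 ± 0.08), DEPP1 (-0.60 ± 0.13), ID1 (-0.59 ± 0.03), FRMD6-AS1 (-0.58 ± 0.12) and ODAPH (-0.56 ± 0.12). ODAPH missed the threshold without 0 h replicate 3 or 4 or 3 h replicate 1 (adjusted p = 0.0546, 0.0512 and 0.0521, range 0.00226 to 0.309). ID1, ID2 and ID3 encode inhibitors of basic helix-loop-helix transcription factors and are known targets of BMP signalling. They account for the 3 members that fell among 14 mineralisation genes, of which 2 rose (2 and 4 when adjusted over the list alone). That list moved down with camera adjusted p = 0.025, a call lost with an estimated correlation (adjusted p = 0.35). It was also lost with the replicate number as a block (adjusted p = 0.071) and without 0 h replicate 2 or 3 h replicate 1 (adjusted p = 0.065 and 0.064), over a range of 0.00074 to 0.35 across its alternatives. Of 9 metallothionein and zinc export genes 0 rose and 1 fell, the zinc exporter gene SLC30A1 (-0.29 ± 0.04). The list moved down (adjusted p = 0.018), a call lost with an estimated correlation (adjusted p = 0.64). It was lost as well without 0 h replicate 1 or 3 h replicate 4 (adjusted p = 0.056 and 0.073, range 0.0047 to 0.64). Adjusted over the list alone, 3 of the 9 fell, and the metallothionein genes are close paralogs whose probes may share signal. None of the 24 ribosome biogenesis genes passed singly, in the whole set or adjusted over the list alone. As a whole the list moved up by a mean of 0.06 (adjusted p = 0.0011, and adjusted p = 0.42 with an estimated correlation). Of 22 alternatives, 8 ended the call of the mineralisation list, 7 that of the metallothionein list and 3 that of the ribosome biogenesis list. TRPM8 was well above background on all 4 arrays at 3 h and on none at 0 h and was at least 1.67-fold higher (adjusted p = 0.034). ADAMTS15 (adjusted p = 0.77) and, in the other direction, EOLA1-DT (adjusted p = 0.11) showed the same split without passing the test.

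The means of the other lists that passed at 3 h, within slides 1 and 2, were 0.19 and 0.14 for ATF4 targets, 0.14 and 0.14 for hypoxia and glycolysis and 0.07 and 0.05 for ribosome biogenesis. They were -0.20 and -0.11 for mineralisation and -0.06 and -0.11 for metallothioneins. The camera adjusted p of these 5 lists with slide as a block lay between 5.2e-07 and 0.0501, and only mineralisation missed the threshold. In the unscaled table the means were 0.11 for ribosome biogenesis, -0.10 for mineralisation and -0.034 for metallothioneins, the last no longer past the threshold (adjusted p = 0.068). Normexp background correction moved several single genes by more than 1.5 times, to 0.61 for NR4A3, 0.38 for SPRY4, -0.48 for SMAD9, -0.42 for VXN, -0.28 for DEPP1 and -0.25 for ODAPH. It ended the calls of FRMD6-AS1 (-0.17, adjusted p = 0.10) and EGLN3 (0.20, adjusted p = 0.10).

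In all, 766 of the 14679 genes passed at 3 h against 0 h, 425 higher and 341 lower, and 10 of them changed at least 2-fold. With slide as a block 976 genes passed, including 764 of these, and within slides 1 and 2 alone 55 and 31 passed. Scaling by the array median, a dim level (at most 49.2% of probes well above background), left 33 genes (26 higher, 7 lower). Unscaled, 117 passed (96 higher, 21 lower). Fitting these groups alone gave 393, a test against a fold of 1.2 gave 29 and the attachment order 2.

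At 6 h against 0 h, the next time, the immediate early genes were still high. NR4A3 was higher by 2.75 ± 0.12 (adjusted p = 1.8e-09), FOS by 2.57 ± 0.04, FOSB by 1.88 ± 0.08, DUSP5 by 1.44 ± 0.06 and EGR1 by 1.11 ± 0.06. Of the 24 genes of the list 22 rose and 0 fell (22 and 0 when adjusted over the list alone). For this list camera gave adjusted p = 1.2e-41, and adjusted p = 4.5e-05 with an estimated correlation. The mean change was 0.69, with means of 0.73 and 0.66 within slides 1 and 2. The non-coding RNA gene CCAT1, a member of no list used here, rose by 1.31 ± 0.13.

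Of the 22 ATF4 targets 10 rose and 0 fell at 6 h (11 and 0 when adjusted over the list alone). The ATF4 list had camera adjusted p = 5.7e-11, and adjusted p = 0.00076 with an estimated correlation. ATF3 rose by 1.91 ± 0.05 (0.39 to 2.02 for its other probes), CHAC1 by 0.78 ± 0.04, DDIT3, the gene of the transcription factor CHOP, by 0.72 ± 0.05, and DDIT4 by 0.62 ± 0.02. Of the 20 hypoxia and glycolysis genes 10 rose and 0 fell (11 and 1 when adjusted over the list alone). That of hypoxia had camera adjusted p = 4.4e-08, and adjusted p = 0.033 with an estimated correlation. The examples were ANGPTL4 (1.05 ± 0.07), HK2 (0.50 ± 0.05), the vasodilator peptide gene ADM (0.49 ± 0.05) and PFKFB4 (0.44 ± 0.04). Among 21 inflammatory cytokine and NF-kB genes 9 rose and 2 fell (9 and 2 when adjusted over the list alone). Among them were IL11 (1.12 ± 0.04), CXCL8 (0.74 ± 0.06), IL6 (0.72 ± 0.06) and CXCL2 (0.47 ± 0.04). The list moved up with camera adjusted p = 1.2e-05, and adjusted p = 0.092 with an estimated correlation. Of 24 ribosome biogenesis genes 9 rose and 1 fell (10 and 1 when adjusted over the list alone), such as RRP12 (0.33 ± 0.09) and NOP2 (0.17 ± 0.04). The list had camera adjusted p = 3.5e-05, and adjusted p = 0.18 with an estimated correlation. RRP12 missed the threshold without 0 h replicate 2 or 4 or 6 h replicate 2 or 4 (adjusted p between 0.0578 and 0.0695, range over its alternatives 0.00143 to 0.42).

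Lists that moved down at 6 h did so by small amounts, and each lost its call with an estimated correlation. Of 14 heat shock genes 0 rose and 5 fell (0 and 9 when adjusted over the list alone). They included HSP90AA1 (-0.24 ± 0.05), HSPA1A (-0.23 ± 0.04, a gene with a near-identical copy, HSPA1B), HSPB1 (-0.19 ± 0.04) and HSPA8 (-0.16 ± 0.04). HSP90AA1 missed the threshold as the median of its probes (-0.15, adjusted p = 0.19). Camera gave adjusted p = 1.3e-05 and, with an estimated correlation, adjusted p = 0.10. Of 9 metallothionein and zinc export genes 0 rose and 4 fell (0 and 7 when adjusted over the list alone). These were MT1F (-0.25 ± 0.04), MT1X (-0.22 ± 0.05), SLC30A1 (-0.19 ± 0.04) and MT1M (-0.16 ± 0.04). The list had adjusted p = 4.3e-05 and, with an estimated correlation, adjusted p = 0.21. Of 24 mitosis genes 0 rose and 2 fell (1 and 2 when adjusted over the list alone), KIF20A (-0.25 ± 0.04) and CCNB2 (-0.13 ± 0.03). For mitosis genes camera gave adjusted p = 0.013 and, with an estimated correlation, adjusted p = 0.33. Of 28 cytosolic ribosomal protein genes 0 rose and 3 fell (0 and 3 when adjusted over the list alone), RPS2 (-0.23 ± 0.05), RPS6 (-0.15 ± 0.04) and RPL4 (-0.11 ± 0.03). RPS2 missed it as the median of its probes (-0.077, adjusted p = 0.19). For this list the values were adjusted p = 5.9e-05 and, with an estimated correlation, adjusted p = 0.48. The direction of this list turned under quantile normalization (camera upwards, adjusted p = 0.365, range over its alternatives 2.6e-06 to 0.484). In the unscaled table, where the median of all tested genes rose by 0.15 at 6 h, the means of the heat shock, metallothionein, mitosis, mineralisation and ribosomal protein lists were above 0, at 0.045, 0.011, 0.11, 0.0037 and 0.084. So were HSPA8 (0.015), MT1M (0.0093), CCNB2 (0.039), RPS6 (0.017) and RPL4 (0.057). Without single arrays, MT1X missed the threshold (0 h replicate 1, 6 h replicate 3 or 4, highest adjusted p = 0.058). So did MT1M (0 h replicate 1 or 3, 6 h replicate 4, highest 0.0551) and RPL4 (0 h replicate 1, 3 or 4, 6 h replicate 1, 2 or 3, highest 0.112). Mineralisation genes went both ways (2 rose and 5 fell of 14, also when adjusted over the list alone), with ID2 (-0.89 ± 0.03), ID3 (-0.76 ± 0.05), ID1 (-0.70 ± 0.03) and PHEX (-0.31 ± 0.07) lower. That list had adjusted p = 0.029, which became 0.23 with an estimated correlation. It was 0.056 with the replicate block, 0.065 without 0 h replicate 2 and 0.070 without 6 h replicate 4, over a range of 0.00016 to 0.23. Of 22 alternatives, 8 ended the call of the mineralisation list, 5 that of the mitosis list and 3 that of the ribosomal protein list besides the turn.

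The largest falls at 6 h were in LNCRNA-IUR (-1.77 ± 0.16), RNA18SN5, a copy of the 18S ribosomal RNA gene (-1.25 ± 0.28), SMAD9 (-1.03 ± 0.08) and ID2, and further in DEPP1 (-0.86 ± 0.13), GPR37L1 (-0.84 ± 0.12), CD86 (-0.84 ± 0.21) and LRRC32 (-0.82 ± 0.11). CD86 missed the threshold without 0 h replicate 3 or 6 h replicate 2 (adjusted p = 0.0619 and 0.0554, range over its alternatives 0.00109 to 0.295). HMOX1, which encodes haem oxygenase 1, was lower by 0.41 (-0.41 ± 0.04, adjusted p = 7.5e-06). Singly, SNAI2 (0.77 ± 0.05), PLK3 (0.56 ± 0.04), SOX9 (0.58 ± 0.06), GDF15 (0.79 ± 0.05) and F3 (0.45 ± 0.04) rose, while DAB2 (-0.33 ± 0.05) and SMAD7 (-0.34 ± 0.04) fell. RAB38, ARMC3 and RAX2 were well above background on all 4 arrays at 6 h and on none at 0 h. They were at least 1.63-fold, 1.45-fold and 1.38-fold higher (adjusted p = 0.0036, 0.020 and 0.0039). THRB-AS1, with the opposite split, did not pass (adjusted p = 0.055).

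The means of the other lists that passed at 6 h, within slides 1 and 2, were 0.29 and 0.26 for ATF4 targets, 0.23 and 0.18 for hypoxia and glycolysis, 0.23 and 0.25 for inflammatory genes and 0.08 and 0.07 for ribosome biogenesis. They were -0.10 and -0.15 for heat shock, -0.14 and -0.18 for metallothioneins, -0.04 and -0.07 for mitosis, -0.04 and -0.13 for ribosomal proteins and -0.19 and -0.14 for mineralisation. The adjusted p of these 9 lists with slide as a block lay between 4.2e-10 and 0.0439. Unscaled, the means of the lists that moved up were 0.45 for ATF4 targets, 0.41 for inflammatory genes, 0.38 for hypoxia and glycolysis and 0.25 for ribosome biogenesis. After normexp correction NR4A3 was at 1.28, LNCRNA-IUR at -0.996, CCAT1 at 0.49, SMAD9 at -0.59, GPR37L1 at -0.55, CD86 at -0.55, DEPP1 at -0.41 and NOP2 at 0.28. The calls of DAB2 (-0.17), RPS2 (-0.15), MT1M (-0.10), RPL4 (-0.035) and RPS6 (-0.014) were then lost. In the unscaled table RRP12 was at 0.50, NOP2 at 0.34 and HMOX1 at -0.24. There the calls were lost of SMAD7 (-0.17), DAB2 (-0.16), PHEX (-0.13), MT1F (-0.081), KIF20A (-0.076), HSP90AA1 (-0.066), RPS2 (-0.061), HSPA1A (-0.054), MT1X (-0.047), SLC30A1 (-0.021) and HSPB1 (-0.019). Quantile normalization left HSP90AA1 at -0.15 and ended the calls of HSPB1 (-0.081), RPS2 (-0.048), RPL4 (-0.046) and RPS6 (-0.038).

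Altogether 1593 genes passed at 6 h against 0 h, 787 higher and 806 lower, 22 of them at least 2-fold. With slide as a block 1927 passed, including 1592 of these, and 294 and 135 passed within slides 1 and 2. Scaling by the array median left 126 genes (85 higher, 41 lower), the unscaled table gave 2412 (2354 higher, 58 lower), a test against a fold of 1.2 gave 95 and the attachment order 133.

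**Figure D3:**
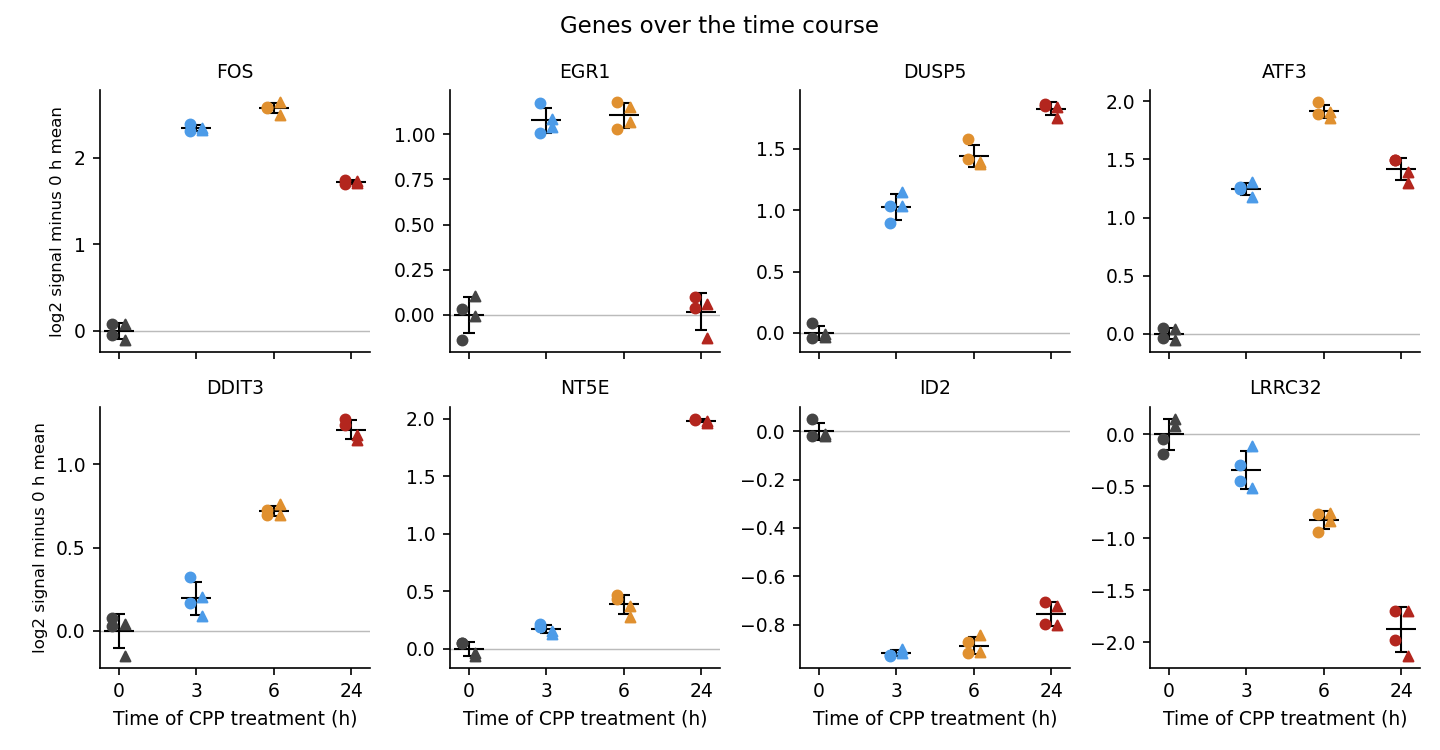
log2 signal of 8 genes on each array minus the gene's mean at 0 h, against time of CPP treatment, with circles for slide 1, triangles for slide 2 and bars for the mean and SD of 4 arrays (arrays grouped by the value table). EGR1 was 1.08 higher at 3 h and 0.02 at 24 h, whereas DUSP5 was 1.03 and 1.83 higher.

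At 24 h against 0 h, the longest treatment, the largest rises were in CCAT1 (2.92 ± 0.13, adjusted p = 5.4e-10), NR4A3 (2.00 ± 0.12), NT5E, the gene of the AMP-hydrolysing surface enzyme CD73 (1.98 ± 0.04) and ANGPTL4 (1.97 ± 0.07). Next came DUSP5 (1.83 ± 0.06), THBD, the gene of thrombomodulin (1.72 ± 0.05), FOS (1.72 ± 0.04) and G0S2, an inhibitor of triglyceride breakdown (1.70 ± 0.05). Of the 24 immediate early and MAPK feedback genes 20 rose and 1 fell (20 and 1 when adjusted over the list alone), with camera adjusted p = 7.2e-14 and adjusted p = 0.0046 with an estimated correlation. PHLDA1 (1.68 ± 0.07) and the ERK phosphatase gene DUSP6 (1.48 ± 0.09) were among them, while EGR1 was at 0.02 (adjusted p = 0.85). The mean change of the list was 0.73, with means of 0.73 and 0.74 within slides 1 and 2.

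Of the 22 ATF4 targets 18 rose and 1 fell at 24 h (19 and 1 when adjusted over the list alone), with camera adjusted p = 1.6e-10 and adjusted p = 0.0018 with an estimated correlation. ATF3 (1.42 ± 0.05), PPP1R15A (1.23 ± 0.05), DDIT3 (1.21 ± 0.05) and the asparagine synthetase gene ASNS (0.88 ± 0.04) were examples. The mean change was 0.48, with means of 0.49 and 0.48 within slides 1 and 2. Ribosome biogenesis genes rose in 18 of 24 cases with 0 falling (20 and 0 when adjusted over the list alone). Examples were RRP12 (0.66 ± 0.09), RRP9 (0.45 ± 0.03), NOP2 (0.40 ± 0.04) and MYBBP1A (0.38 ± 0.03). The list had camera adjusted p = 3.1e-09, and adjusted p = 0.046 with an estimated correlation.

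Cholesterol synthesis and uptake genes, the targets of the transcription factor SREBF2, fell at 24 h in 17 of 25 cases and rose in 1 (18 and 1 when adjusted over the list alone). Camera gave the list adjusted p = 3.2e-07, and adjusted p = 0.013 with an estimated correlation. MSMO1 (-0.43 ± 0.04), MVK (-0.41 ± 0.04) and HSD17B7 (-0.40 ± 0.04) were lower. The mean of the list fell by 0.20, with means of -0.21 and -0.20 within slides 1 and 2. The cholesterol exporter gene ABCA1 rose by 0.65 ± 0.04, although the list of LXR targets did not pass (3 rose and 0 fell of 8, adjusted p = 0.49). Of 34 lysosome genes 16 rose and 2 fell (18 and 2 when adjusted over the list alone), among them the channel gene MCOLN1 (0.40 ± 0.06), NEU1 (0.38 ± 0.04), the cholesterol transporter gene NPC1 (0.36 ± 0.03) and SGSH (0.36 ± 0.04). The lysosome list moved up with camera adjusted p = 9.2e-05, and adjusted p = 0.15 with an estimated correlation, with mean changes of 0.15 and 0.13 within slides 1 and 2.

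Among cytokine and interferon genes at 24 h, 11 of 21 inflammatory cytokine and NF-kB genes rose and 5 fell (11 and 5 when adjusted over the list alone). They included CSF2 (1.04 ± 0.10), CXCL8 (0.81 ± 0.06), IL6 (0.78 ± 0.06) and TNFAIP3 (0.73 ± 0.05). That list's camera adjusted p of 0.047 became 0.080 with the replicate block, 0.068 with the slide block and 0.47 with an estimated correlation. It lay between 0.0501 and 0.0605 without any of 0 h replicates 1 and 2 and 24 h replicates 1, 2 and 4, over a range of 0.010 to 0.47 over its alternatives, of which 13 of 22 ended the call. Of 18 type I interferon genes 9 rose and 3 fell (9 and 3 when adjusted over the list alone), with OASL (1.14 ± 0.10), IFI44L (0.89 ± 0.04), IFIT3 (0.72 ± 0.03) and IFIT1 (0.69 ± 0.07) highest. For interferon genes camera gave adjusted p = 0.035, and adjusted p = 0.23 with an estimated correlation and 0.13 within slide 2 alone. GDF15 (1.64 ± 0.05), PMAIP1 (0.80 ± 0.05), the autophagy receptor gene SQSTM1 (0.56 ± 0.07), IL18 (0.69 ± 0.03) and TXNRD1 (0.62 ± 0.03) rose without their lists passing. So did OSGIN1 (0.62 ± 0.09), ADM (0.82 ± 0.05), ARRB1 (0.59 ± 0.06) and ATP2B1 (0.67 ± 0.05). HRK was 1.92 ± 0.43 higher but well above background on only 2 of 4 arrays at 0 h, with 0 h replicate 1 at -2.44 and a median of -4.25 in the others, so the size of its rise is uncertain. It missed the threshold within slide 1 alone (adjusted p = 0.15). BCL2, an inhibitor of apoptosis, was 0.75 lower (-0.75 ± 0.05).

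Of 15 proximal tubule markers 1 rose and 6 fell (1 and 6 when adjusted over the list alone). Among these were the cation transporter gene SLC22A2 (-0.90 ± 0.19, well above background on 2 of 4 arrays at 24 h), the endocytic adaptor gene DAB2 (-0.71 ± 0.05), CDH6 (-0.59 ± 0.05) and SLC3A1 (-0.52 ± 0.08). The list's camera adjusted p of 0.047 became 0.15 with an estimated correlation. It was 0.060, 0.056, 0.051 and 0.065 without 0 h replicates 2 or 4 or 24 h replicates 1 or 2, over a range of 0.0064 to 0.15 over its alternatives, of which 10 of 22 ended the call. Of 23 matrix and TGF-beta targets 4 rose and 12 fell (4 and 14 when adjusted over the list alone). Those that fell included COL1A1 (-0.92 ± 0.04), COL5A1 (-0.65 ± 0.11), TGFB2 (-0.59 ± 0.06) and ACTA2 (-0.41 ± 0.08). Matrix genes had camera adjusted p = 0.034, and adjusted p = 0.47 with an estimated correlation. That call was also lost with median scaling (mean -0.075, adjusted p = 0.092) and within slide 2 alone (adjusted p = 0.070). Beside them, of 5 markers of fibroblasts 0 rose and 1 fell, POSTN (-0.98 ± 0.09), and that list did not pass (adjusted p = 0.48). Of 24 mitosis genes 1 rose and 12 fell (1 and 12 when adjusted over the list alone). The falls were small, as in KIF20A (-0.30 ± 0.04), HMMR (-0.28 ± 0.06), NUSAP1 (-0.28 ± 0.04) and CENPF (-0.22 ± 0.04). For mitosis genes camera gave adjusted p = 0.00095, and adjusted p = 0.22 with an estimated correlation. With median scaling it gave adjusted p = 0.11 (mean -0.066). Mineralisation genes again went both ways, with 4 of 14 higher and 7 lower (4 and 7 when adjusted over the list alone). BMP4 (-0.78 ± 0.05), ID2 (-0.76 ± 0.03), PHEX (-0.73 ± 0.07) and ID3 (-0.71 ± 0.05) fell most. Their camera adjusted p was 0.038, and 0.23 with an estimated correlation, 0.059 without 0 h replicate 2 and 0.053 without 24 h replicate 2, over a range of 0.010 to 0.23 over its alternatives, of which 7 of 22 ended the call. The means within slides 1 and 2 were 0.24 and 0.25 for ribosome biogenesis, 0.20 and 0.27 for inflammatory genes and 0.27 and 0.20 for interferon genes. They were -0.09 and -0.12 for mitosis, -0.11 and -0.12 for matrix genes, -0.25 and -0.22 for proximal tubule markers and -0.14 and -0.08 for mineralisation. In the unscaled table, where each kept its call, the means were -0.016 for mitosis, -0.024 for matrix genes, -0.15 for proximal tubule markers and -0.020 for mineralisation, beside -0.11 for cholesterol and 0.23 for lysosome genes. Of the 11 lists that passed, the inflammatory list alone missed the threshold with slide as a block, the others lying between 5.1e-13 and 0.0439.

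The largest single falls at 24 h were in LRRC32 (-1.88 ± 0.11), GPR37L1 (-1.71 ± 0.12), RNA18SN5 (-1.62 ± 0.28) and MGAT4C (-1.56 ± 0.06). They were followed by the WNT pathway gene DACT1 (-1.46 ± 0.04), NEBL (-1.41 ± 0.11), the epithelial polarity gene LLGL2 (-1.41 ± 0.07) and the potassium channel gene KCNJ2 (-1.40 ± 0.05). CD24 (-1.10 ± 0.03), PDZK1 (-0.69 ± 0.04), TPM1 (-0.54 ± 0.06), MT1F (-0.47 ± 0.04), THBS1 (-0.45 ± 0.06) and LRP1 (-0.47 ± 0.05) fell in lists that did not pass. So did VCAM1, well above background on all 4 arrays at 0 h and on none at 24 h and at least 1.49-fold lower (adjusted p = 7.7e-06). Normexp correction left it at -0.30, short of the bound (log2 0.57). WNT11, ATOH8 and LUARIS, with the same split, were at least 3.27-fold, 2.51-fold and 2.10-fold lower (adjusted p = 1.0e-07, 6.1e-06 and 8.6e-06). AEBP1, ARB2BP and MSRB3-AS1 showed the opposite split and were at least 1.94-fold, 1.76-fold and 1.76-fold higher. Each bound sets the mean of the brighter arrays against, on each dimmer array, the higher of the lowest signal well above background and the probe's own signal, which for ARMC3 gives the measured difference.

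Of the remaining lists at 24 h, hypoxia and glycolysis genes split into 6 higher and 6 lower of 20 (adjusted p = 0.83), with a mean of 0.16 and a median of -0.02. The lists of oxidative stress (6 higher and 1 lower of 21), p53 (7 and 7 of 21), apoptosis (6 and 3 of 22) and DNA replication genes (6 and 4 of 26) did not pass. Nor did those of autophagy (4 and 4 of 20), unfolded protein response (5 and 4 of 17), heat shock (3 and 2 of 14) and metallothionein genes (3 and 1 of 9). Neither did those of ribosomal protein (2 and 2 of 28), oxidative phosphorylation (1 and 4 of 27) and YAP and serum response factor genes (3 and 7 of 17). The same held for tubule injury (6 and 4 of 18), phosphate and calcium handling (7 and 4 of 18), membrane trafficking (5 and 3 of 23) and inflammasome genes (1 and 0 of 4). Markers of other cell types also did not pass, with 1 higher and 0 lower of 4 for distal nephron, 1 and 1 of 4 for endothelium and 0 and 1 of 7 for leukocytes. A list's median, mean and test direction differed in sign for 7 lists at 3 h, 4 at 6 h and 4 at 24 h, none of which passed.

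In total 5816 genes passed at 24 h against 0 h, 3037 higher and 2779 lower, of which 158 changed at least 2-fold, so most changes were small (median absolute change 0.24). With slide as a block 6317 passed, including 5793 of these, and 3494 and 2841 passed within slides 1 and 2, 2106 of them in both. Scaling by the array median left 1271 genes, and 3842 passed in the unscaled table (2934 higher, 908 lower). A test against a fold of 1.2 gave 934 and the attachment order 185. After normexp correction 39 changed at least 2-fold. Among genes named above it moved CCAT1 to 1.54, DUSP6 to 0.98, NR4A3 to 0.80, HRK to 0.49, OSGIN1 to 0.41 and OASL to 0.37. Of those that fell it moved LRRC32 to -1.05, MGAT4C to -0.93, GPR37L1 to -0.88, LLGL2 to -0.85, NEBL to -0.62 and POSTN to -0.54. COL5A1 was then at -0.38, SLC3A1 at -0.30, ACTA2 at -0.22 and SLC22A2 at -0.22, and each of these 16 kept its call. CENPF lost its call in the unscaled table (-0.13, adjusted p = 0.21).

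**Figure D4:**
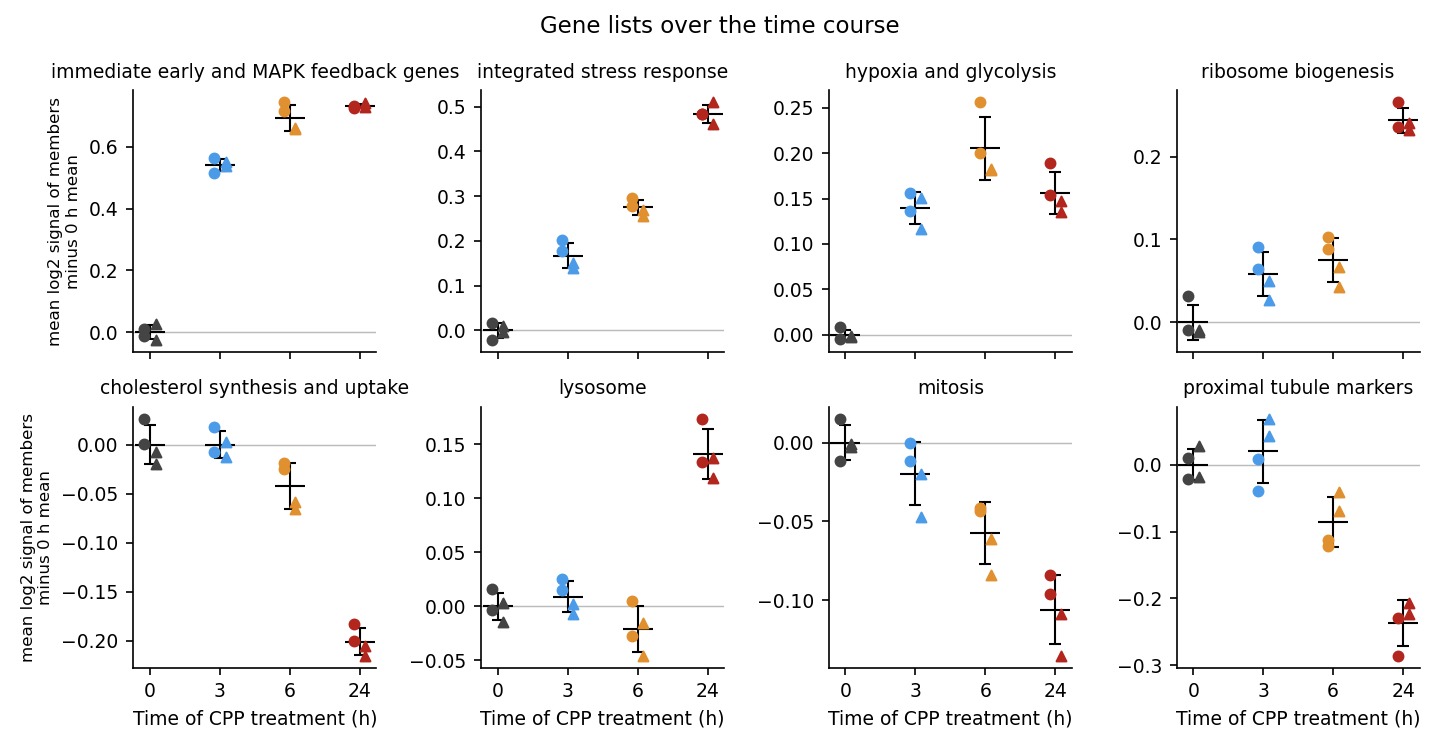
Mean log2 signal of the tested members of 8 gene lists on each array, minus the mean at 0 h, against time of CPP treatment, with circles for slide 1, triangles for slide 2 and bars for the mean and SD of 4 arrays (arrays grouped by the value table). The immediate early list was 0.54 higher at 3 h and 0.73 at 24 h, and the cholesterol list was 0.20 lower at 24 h (-0.20).

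Between 6 h and 24 h, a comparison that shares no array with 3 h against 0 h, the largest rises were in CCAT1 (1.61 ± 0.13), NT5E (1.60 ± 0.04), BEX2 (1.26 ± 0.04) and the matricellular protein gene CCN3 (1.25 ± 0.05). Among the largest falls were ZNF157 (-1.24 ± 0.12), CILP (-1.17 ± 0.06) and SLCO5A1 (-1.16 ± 0.20). After normexp correction CCAT1 was at 1.06 and SLCO5A1 at -0.58. Lysosome genes rose (22 of 34, 0 fell, 23 and 0 when adjusted over the list alone, camera adjusted p = 4.4e-07, and adjusted p = 0.090 with an estimated correlation). Cholesterol synthesis genes fell (14 of 25, 0 rose, 14 and 1 when adjusted over the list alone), with camera adjusted p = 1.5e-07 and adjusted p = 0.024 with an estimated correlation. Of the ATF4 targets 13 of 22 rose and 2 fell (14 and 2 when adjusted over the list alone), with camera adjusted p = 0.00023 and adjusted p = 0.047 with an estimated correlation. The means within slides 1 and 2 were 0.17 and 0.16 for lysosome genes, -0.17 and -0.15 for cholesterol genes and 0.20 and 0.22 for ATF4 targets. The lists of heat shock (10 rose and 1 fell of 14), interferon (8 and 1 of 18), ribosome biogenesis (17 and 0 of 24), ribosomal protein (6 and 0 of 28) and metallothionein genes (5 and 1 of 9) moved up. With an estimated correlation these calls were lost, at adjusted p = 0.27, 0.10, 0.10, 0.84 and 0.58. Those of YAP and serum response factor targets (0 rose and 9 fell of 17), matrix genes (2 and 6 of 23), proximal tubule markers (1 and 7 of 15) and mitosis genes (0 and 4 of 24) moved down. These too were lost with an estimated correlation, at adjusted p = 0.20, 0.50, 0.10 and 0.46. Adjusted over the list alone, rises and falls in the lists that moved up were 11 and 1, 8 and 1, 19 and 0, 4 and 0, and 6 and 1, in the same order. In those that moved down they were 0 and 9, 2 and 6, 1 and 7, and 0 and 4. Camera adjusted p of these 9 lists lay between 4.4e-07 and 0.0353. In the same order, their means within slides 1 and 2 were 0.12 and 0.16, 0.22 and 0.21, 0.16 and 0.18, 0.03 and 0.10, and 0.12 and 0.14 for rises. For falls they were -0.20 and -0.14, -0.10 and -0.09, -0.14 and -0.16, and -0.05 and -0.05. In the unscaled table the mean of the ribosomal protein list was -0.016 (camera adjusted p = 0.43, range over its alternatives 0.0052 to 0.84). Without single arrays the calls were lost of metallothioneins (6 h replicate 3 or 4, 24 h replicate 2 or 4, highest adjusted p = 0.0727) and ribosomal proteins (the same arrays, highest 0.118). The same was true of proximal tubule markers (6 h replicate 4, 24 h replicate 2, highest 0.0575), matrix genes (6 h replicate 2, 24 h replicate 3, highest 0.0552) and mitosis genes (24 h replicate 4, 0.0612). Median scaling ended the calls of metallothioneins (adjusted p = 0.18), ribosomal proteins (0.31), mitosis (0.31) and matrix genes (0.080). The immediate early list did not pass (9 rose and 6 fell of 24, 10 and 7 when adjusted over the list alone, adjusted p = 0.84). In this comparison 4390 genes passed, 2552 higher and 1838 lower at 24 h, 52 of them at least 2-fold. With slide as a block 4883 passed, and 2016 and 1356 within slides 1 and 2. Scaling by the array median left 591 genes (253 higher, 338 lower), and 1793 passed in the unscaled table (391 higher, 1402 lower). A test against a fold of 1.2 gave 434 and the attachment order 0 (265 at an unadjusted p below 0.05).

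Genes called early were called late in the same direction more often than independent lists would be. Of 425 genes that rose at 3 h against 0 h, 168 also rose at 24 h against 6 h, against 73.9 for independent lists (Fisher's exact test, p = 6.1e-28, adjusted p = 2.4e-27). Another 73 fell, against 53.2 (adjusted p = 0.0061). Of 341 genes that fell early, 110 also fell late, against 42.7 (adjusted p = 8.5e-22), and 54 rose, against 59.3 (adjusted p = 0.47). The comparisons share no array, but both come from 1 fit and share each gene's estimated spread. Genes with a small spread are called more easily in both, so overlaps can exceed those of independent lists without related changes. Each comparison also sets neighbouring slide columns against each other. Genes are not independent replicates either, so these p-values overstate the precision. The total of 405 overlapping genes became 10 with median scaling, 56 in the unscaled table, 253 after normexp correction, 41 and 19 within slides 1 and 2, and 0 under the attachment order.

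Between 3 h and 6 h the difference was smaller, with 250 genes past the threshold, 145 higher and 105 lower at 6 h, of which 2 changed at least 2-fold. NR4A3 (1.21 ± 0.12) and LNCRNA-IUR (-1.68 ± 0.16), chosen after their values were seen, were the pair that changed at least 2-fold (0.67 and -0.97 after normexp correction). Immediate early genes (7 rose and 0 fell of 24), ATF4 targets (5 and 0 of 22) and inflammatory genes (7 and 0 of 21) were higher at 6 h than at 3 h. Adjusted over the list alone, the rises and falls were 14 and 0, 8 and 2, and 9 and 1. Their camera adjusted p was 1.6e-12, 1.8e-05 and 5.2e-08, and their adjusted p = 0.0139, 0.0196 and 0.0345 with an estimated correlation. Their means within slides 1 and 2 were 0.19 and 0.12, 0.10 and 0.12, and 0.16 and 0.11. Another 8 of the 11 lists that passed lost their call with an estimated correlation, at an adjusted p between 0.0552 and 0.432. Of these, hypoxia and glycolysis genes (2 rose and 0 fell of 20) moved up, and 7 lists moved down with at most 1 member falling, although their means lay above 0 in the unscaled table (0.013 to 0.081, where the median of all genes rose by 0.11). The ribosomal protein list among them turned upwards under quantile normalization (mean 0.014). Without single arrays the calls were lost of the unfolded protein response (3 h replicate 1 or 2, 6 h replicate 3 or 4, highest adjusted p = 0.131), metallothionein (the same arrays, highest 0.0813), mitosis (3 h replicate 1, 2 or 4, 6 h replicate 4, highest 0.110) and hypoxia lists (6 h replicate 2, 0.0721). The mitosis list also missed the threshold with the replicate block (adjusted p = 0.054, range over its alternatives 0.0155 to 0.793, of which 13 of 22 ended the call). The count was 378 with slide as a block, 262 with the replicate block, and 6 and 1 within slides 1 and 2. It dropped to 158 and 153 without 3 h replicates 2 and 3, and to 146, 128 and 137 without 6 h replicates 1, 2 and 3. It was 8 with median scaling (6 higher, 2 lower) and 88 in the unscaled table (85 higher, 3 lower). It was 95 in a fit of these groups alone (69.5% higher), 134 after normexp correction and 189 under the attachment order.

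Of the 32 lists, 6, 10 and 11 passed at 3, 6 and 24 h against 0 h, 12 at 24 h against 6 h and 11 at 6 h against 3 h. With an estimated correlation 3, 3, 4, 2 and 3 passed.

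Over all times, 6114 of the 14679 genes passed the moderated F-test against 0 h, and 167 of them changed at least 2-fold at some time. The count was 6764 with slide as a block, 2627 and 1744 within slides 1 and 2, 999 with median scaling, 3854 in the unscaled table and 233 under the attachment order.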

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

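Tests of 24 h against 3 h and the counts over probes without a gene name were chosen after the data were seen, and the search for single arrays far from their group was set beforehand. Only genes named were searched for reversals. In 5, changes from 0 h early and at 24 h had opposite signs, both past the threshold and differing by limma. HMOX1, the haem oxygenase gene, was at -0.19 at 3 h, -0.41 at 6 h and 0.35 at 24 h, differences of 0.54 and 0.76 between 24 h and the earlier times. EGLN3, which encodes an oxygen-sensing prolyl hydroxylase, was at 0.31 and 0.29 and then at -0.37, differences of -0.68 and -0.66. PFKFB4 was at 0.36 and 0.44 and then at -0.19, differences of -0.55 and -0.63. The autophagy gene GABARAPL1 was at 0.20 at 3 h, 0.29 at 6 h and -0.19 at 24 h, differences of -0.39 and -0.48. ANKRD1 was at -0.29 at 3 h and 0.15 at 24 h, a difference of 0.44, but its 3 h call was lost in 5 of 21 alternatives, namely normexp correction (-0.19, adjusted p = 0.059), median scaling, the unscaled table and each slide alone (highest adjusted p = 0.9999). Alternatives also ended the 3 h calls of EGLN3 (10 of 21), GABARAPL1 (4) and PFKFB4 (3), and the 6 h calls of GABARAPL1 (2), HMOX1 (2) and PFKFB4 (1).

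Among genes and lists named, single arrays stood apart from the other 3 of their time in 34 of 808 groups (4.21%), where chance gives about 1 in 20, or 40.4. The value given, for those reported here, is the gap to the nearest array as a share of the group's range, which exceeded Dixon's 95% limit for 4 samples in each case. At 0 h the highest array stood apart for ANGPTL4 (0.874), CYP24A1 (0.918), HRK (0.837), ID2 (0.856), RPL4 (0.839) and the mean of the ribosome biogenesis list (0.937). The lowest did for CSF2 (0.850) and TRPM8 (0.953). At 3 h the highest array stood apart for ADAMTS15 (0.855), ANGPTL4 (0.833), ATP2B1 (0.887), BCL2 (0.878), BEX2 (0.962), CRELD2 (0.837), ULK1 (0.915) and VXN (0.884). The lowest at that time did for CILP (0.858), NR1H3 (0.851), SMPDL3A (0.927) and ZNF157 (0.849). At 6 h it was the highest for CCNE1 (0.936), ODAPH (0.861), RAB38 (0.882), SLC3A1 (0.846) and SLCO5A1 (0.862) and the lowest for DACT1 (0.830), RPL4 (0.936) and TGFB2 (0.893). At 24 h it was the lowest for CCN2 (0.908), DEPP1 (0.833), DUSP5 (0.835), ID1 (0.831) and SLC4A4 (0.947). The widest gaps in log2 signal were in HRK (0 h replicate 1 at -2.44, median of the others -4.25), TRPM8 (0 h replicate 4 at -5.63 and -4.37) and SLCO5A1 (6 h replicate 1 at -0.79 and -1.94).

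Probes without a gene name changed with time as well. Of 6812 such probes that passed the filter, 923 passed limma at 24 h against 0 h, 366 of them higher and 61 at least 2-fold, and 12 and 97 passed at 3 h and 6 h.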

How the results depend on the processing

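Slide as a block, fits within each slide and the attachment order of the arrays were chosen after the data were seen, and the other alternatives were planned. The limits are the order of the arrays, the scaling of arrays against each other, 4 arrays per time, and signal over background, since a gene not well above background on all 4 arrays of some time was not tested, and a group below it gives only a bound. Unless a value or the alternative itself shows why, the cause was not tested. Quantile normalization, the median over a gene's probes, an intensity trend with robust spread and the replicate block kept every count of called genes within 1.5 times of its value. Of 223 results for single genes, slide as a block ended 0 calls, an intensity trend with robust spread 1 (NR1H3 at 6 h), the filter on all 16 arrays 1 of 218, and the median over probes 7. Quantile normalization ended 9, no filter on dim probes 10, fits of only the groups compared 18 and normexp correction 26. The unscaled table ended 55, median scaling 99, and slides 1 and 2 alone 78 and 87, where fewer arrays enter the fit. Leaving out single arrays ended the call of 22 of the 223 in at least 1 fit and turned none of them. Gene values moved by more than 1.5 times in 50 results with normexp correction, 48 in the unscaled table, 8 with quantile normalization, 5 with the median over probes, 2 with median scaling, 5 and 3 within slides 1 and 2, and 1 without a single array. Of 50 list results, median scaling ended 14 calls, quantile normalization 11, the unscaled table and no filter on dim probes 9 each, normexp correction 7, slides 1 and 2 alone 8 and 14, and an estimated correlation 35. List means moved by more than 1.5 times in 40 results in the unscaled table, 8 with quantile normalization, 7 with normexp correction and 5 with median scaling. The F-test was not run with the intensity trend, and the overlap of early and late calls was not counted without single arrays.

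The replicate number as a block gave 830 genes at 3 h, 1781 at 6 h and 6207 at 24 h against 0 h, 4687 at 24 h against 6 h, 262 at 6 h against 3 h and 6518 at any time. It ended the calls of the mineralisation list at 3 h and 6 h (adjusted p = 0.0709 and 0.0561), the inflammatory list at 24 h (0.0802), and the mitosis list at 6 h against 3 h (0.0539), and that of 1 of the 223 gene results. The block changed no other call among the genes and lists named. Lists that passed numbered 5, 9, 10, 12 and 10 with it. With the replicate number or slide as a block, fewer degrees of freedom remain but the difference between slides leaves the spread. Since the attachment order exchanges time and replicate number, this block is also a block for the attached times.

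Median scaling left 33, 126, 1271, 591 and 8 genes at 3 h, 6 h and 24 h against 0 h, 24 h against 6 h and 6 h against 3 h, with 999 at any time and 10 shared by early and late changes. In the unscaled table the counts were 117, 2412, 3842, 1793 and 88, with 3854 at any time and 56 shared. There, at 6 h, 7 genes that had fallen stood above 0, namely CRELD2 (0.0445), HSPA8 (0.0146), MT1M (0.00932), NR1H3 (0.0742), CCNB2 (0.0390), RPS6 (0.0172) and RPL4 (0.0571), none past the threshold. All of these are smaller than the shift of the median gene there (0.15). Quantile normalization turned the ribosomal protein list at 6 h against 0 h (0.0163) and against 3 h (0.0143), and the median over probes turned RPS2 at 24 h (0.0169). After normexp correction 5, 9, 39 and 8 genes changed at least 2-fold at 3, 6 and 24 h against 0 h and 24 h against 6 h, 134 passed at 6 h against 3 h and 253 were shared. Without the filter on dim probes 46, 244 and 86 changed at least 2-fold at 6 h, 24 h and 24 h against 6 h, and 140 passed at 6 h against 3 h, with more genes tested. With only genes above background on all 16 arrays, 6, 14 and 27 changed at least 2-fold at 3 h, 6 h and 24 h against 6 h, with fewer genes tested. Fits of only the groups compared gave 393 at 3 h and 95 at 6 h against 3 h, with fewer arrays. A test against a fold of 1.2 gave 29, 95, 934, 434 and 4, since it asks for more than a difference from 0.

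Slide as a block raised the count at 6 h against 3 h to 378 and ended the calls of the mineralisation list at 3 h (adjusted p = 0.0501) and the inflammatory list at 24 h (0.0679). Within slide 1 alone 55 genes passed at 3 h (5 at least 2-fold), 294 at 6 h, 3494 at 24 h, 2016 at 24 h against 6 h and 6 at 6 h against 3 h, with 2627 at any time and 41 shared. Within slide 2 alone 31, 135, 2841, 1356 and 1 passed, with 14 at least 2-fold at 6 h, 1744 at any time, 19 shared and 6 lists at 24 h. Without single arrays the counts lay between 518 and 610 at 3 h, 1170 and 1303 at 6 h, 5152 and 5414 at 24 h, 3759 and 4007 at 24 h against 6 h, 128 and 213 at 6 h against 3 h and 5292 and 6004 at any time. At least 2-fold they lay between 9 and 12, 19 and 25, 148 and 165, and 51 and 58 in the first 4 comparisons. Lists that passed lay between 5 and 7, 9 and 11, 8 and 11, 9 and 13, and 8 and 11. With an estimated correlation 3, 3, 4, 2 and 3 lists passed camera, in place of 6, 10, 11, 12 and 11. Fry, which tests whether a list's genes move on balance one way and makes no comparison with other genes, passed 8, 14, 18, 21 and 9 of the 32 lists, and 22, 26, 30, 29 and 23 for change in either direction. Both camera and fry passed 5, 10, 11, 12 and 7.

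Grouping by scanner-file attachment gave 2, 133, 185, 0 and 189 genes by limma in the same 5 comparisons, with 268, 1027, 1130, 265 and 1216 at an unadjusted p below 0.05, and 233 at any time. The 133, 185 and 189 came from comparisons between slides under that order, so slide and time cannot be told apart there. Of at least 2-fold there were 0, 25, 36 and 0, early and late changes shared 0 genes, and 0, 3, 0, 0 and 2 lists passed camera, none of them a list that passed in the same comparison by the value table. At an unadjusted p below 0.05 camera gave 0, 3, 3, 2 and 5 lists. Of the 223 gene results 120 kept their sign and 103 did not, nor did 4 of 24 genes chosen after their values were seen. Of 50 list results the camera direction turned in 23 and the mean changed sign in 26, in 10 of them with the direction kept, while in 7 the direction turned and the mean kept its sign. No gene or list result that passed in the value-table order passed in the attachment order, and the lowest adjusted p among those that turned was 0.193. The genes that turned and are reported here follow in log2. For lists whose camera direction turned the mean is given, whether or not its sign changed. At 3 h against 0 h genes that had risen stood below 0 in the case of FOS (-0.058), NR4A3 (-0.21), FOSB (-0.17), EGR1 (-0.032), IL11 (-0.037), TXNRD1 (-0.042), PPP1R15A (-0.039), CHAC1 (-0.037) and IL18 (-0.014). IFIT1 (-0.030), IFIT2 (-0.017), MYLIP (-0.076), GDF15 (-0.018) and PFKFB4 (-0.013) did too. Genes that had fallen in that comparison stood above 0 in the case of ID2 (0.029), DEPP1 (0.043), ID1 (0.0077), FRMD6-AS1 (0.22) and SLC30A1 (0.012). At 6 h against 0 h genes that had risen stood below 0 in the case of NR4A3 (-0.16), FOS (-0.056), ATF3 (-0.064), FOSB (-0.089), DUSP5 (-0.0033), CCAT1 (-0.056), IL11 (-0.016), EGR1 (-0.017) and CHAC1 (-0.027). DDIT3 (-0.085), CXCL8 (-0.087), IL6 (-0.020), IL18 (-0.034), IFIT1 (-0.10), IFIT2 (-0.074), GLA (-0.017), GABARAPL1 (-0.0025) and GDF15 (-0.018) did too. PLK3 (-0.014), TNFRSF10A (-0.11), RRP12 (-0.021), NOP2 (-0.0091), NOLC1 (-0.018), HK2 (-0.062), ADM (-0.071), SNAI2 (-0.088) and F3 (-0.0021) did too. CCN2 (-0.043), ATP2B1 (-0.032) and RCAN1 (-0.014) did too. Genes that had fallen in that comparison stood above 0 in the case of RNA18SN5 (0.087), DEPP1 (0.11), LRRC32 (0.034), HSPA8 (0.052), RPS2 (0.039), RPS6 (0.047), RPL4 (0.060), SMAD7 (0.028) and ID1 (0.014). At 24 h against 0 h genes that had risen stood below 0 in the case of NR4A3 (-0.095), NT5E (-0.10), DUSP5 (-0.0059), THBD (-0.046), FOS (-0.037), TXNRD1 (-0.048), ATF3 (-0.049), PPP1R15A (-0.054) and DDIT3 (-0.13). ASNS (-0.026), MT1B (-0.12), CSF2 (-0.12), CXCL8 (-0.043), IL6 (-0.018), TNFAIP3 (-0.072), IL18 (-0.010), IFI44L (-0.031) and DUSP6 (-0.10) did too. ABCA1 (-0.052), SMPDL3A (-0.071), SGSH (-0.091), HRK (-0.65), RRP12 (-0.043), RRP9 (-0.034), NOP2 (-0.061), EGFL7 (-0.0091), SPRED2 (-0.084) and SPP1 (-0.0034) did too. Genes that had fallen in that comparison stood above 0 in the case of GPR37L1 (0.044), RNA18SN5 (0.23), MGAT4C (0.028), LLGL2 (0.050), KCNJ2 (0.023), HSD17B7 (0.045), ULK1 (0.0056), RPS2 (0.032) and RPL11 (0.024). COL5A1 (0.094), SLC3A1 (0.067), ID2 (0.034), CDH5 (0.17), CD14 (0.034) and LRP1 (0.021) did too. Between 6 h and 24 h genes that had risen stood below 0 in the case of NT5E (-0.033) and TXNIP (-0.042). Genes that had fallen in that comparison stood above 0 in the case of BMP2 (0.012). At 3 h against 0 h the camera direction turned for the lists named ATF4 targets (0.0019), metallothioneins (0.016), immediate early (-0.0097), ribosome biogenesis (-0.0061) and mineralisation (0.029). At 6 h against 0 h the camera direction turned for the lists named ribosome biogenesis (-0.037), cytosolic ribosomal proteins (-0.0093) and mineralisation (-0.00058). At 24 h against 0 h the camera direction turned for the lists named inflammatory (-0.067), interferon (-0.024), cholesterol synthesis (-0.018), ribosome biogenesis (-0.028), proximal tubule markers (0.022) and mineralisation (-0.040). Between 6 h and 24 h the camera direction turned for the lists named ATF4 targets (-0.022), heat shock (-0.0028), interferon (-0.00023), cholesterol synthesis (0.0074), cytosolic ribosomal proteins (-0.026) and matrix and TGF-beta (-0.0014). The list of proximal tubule markers (-0.016) turned as well. At 6 h against 3 h the camera direction turned for the lists named hypoxia and glycolysis (-0.038) and proximal tubule markers (0.070).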

Other observations

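Tests of the attachment order of the arrays, of a brief early response, of positions of single probes and of position for genes changed at least 2-fold were chosen after the results were seen, and so were the genes of this paragraph and the next. By 24 h, against 0 h, the cyclin D1 gene CCND1 rose by 1.36 ± 0.04 on the log2 scale (limma adjusted p = 1.1e-11, n = 4 arrays per time). The transcription factor genes ETV4 and ETV5, known targets of ERK signalling, rose by 1.25 ± 0.06 and 1.04 ± 0.07, and ETV5 had already risen by 0.61 at 3 h. SPRED2, a feedback inhibitor of the same pathway, rose by 0.46 ± 0.06 and the receptor gene EPHA2 by 0.42 ± 0.05. KLF2 rose by 1.02 ± 0.04 and RRAGD, the gene of a GTPase that acts at the lysosome, by 1.02 ± 0.11. Normexp correction moved RRAGD to 0.48 and SMAD9 to -0.71. In the BMP and TGF-beta pathways SMAD9 (-1.32 ± 0.08), SMAD7 (-0.41 ± 0.04) and SMAD6 (-0.33 ± 0.05) fell, beside the falls of ID1, ID2 and ID3. BMP2 was 0.39 higher at 3 h and then dropped between 6 h and 24 h (-0.23).

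Among genes linked to mineral handling and the tubule, KL, the gene of klotho (-0.52 ± 0.06), ENPP1, whose enzyme makes the mineralisation inhibitor pyrophosphate (-0.53 ± 0.04), and the tubule injury marker HAVCR1 (-0.39 ± 0.06) fell at 24 h. SPP1, the gene of osteopontin (0.30 ± 0.02), and the phosphate transporter gene SLC20A1 (0.34 ± 0.04) rose. TXNIP, which encodes a thioredoxin inhibitor, was lower at 3 h (-0.40 ± 0.07) and 6 h (-0.41 ± 0.07) and higher at 24 h than at 6 h (0.50 ± 0.07). Of the 24 results of this kind, 12 kept their call in each of up to 21 alternatives. The other 12 lost it only with median scaling, in the unscaled table or within single slides. The highest adjusted p was 0.896 for TXNIP at 3 h, 0.548 for BMP2 at 24 h against 6 h and 0.454 for BMP2 at 3 h and TXNIP at 6 h. For SMAD6 and HAVCR1 at 24 h it was 0.222 and 0.137. None passed under the attachment order, which turned SPP1, SPRED2, TXNIP at 24 h against 6 h and BMP2 at 24 h against 6 h.

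Within each comparison, other splits of the same 8 arrays gave far fewer genes than the split by time. In mixed splits the difference between times enters the spread, which itself lowers their counts. The value-table order was chosen after counts under both orders had been seen, so this is no independent evidence for that order. Replicates may be technical, so chance differences between cultures stay open. Of the 35 ways to split the 8 arrays of a comparison into 4 and 4, only 1, the real one, gave as many genes as the 766, 1593, 5816, 4390 and 250 called by limma. The highest other counts were 6, 1, 0, 6 and 1, and each 6 came from the split by slide. Among the 8 splits that part every pair of equal replicate number, the highest other count was 0 in each comparison. For any time 1 of 100 drawn splits of the 16 arrays, the real one, reached 6114 genes, and the highest other gave 1. Shuffles of the times within replicate numbers, which can leave arrays at their own time, gave at most 3755 in 100 draws.

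The large effect of time appears only with the value-table order of the arrays, under which each time fills a column of the slides. The tables argue against position acting on single probes, since 86.9% of 1590 called genes with another tested probe elsewhere on the array moved the same way there at 24 h, against at most 55.4% in 1000 shuffles. All 7 spike-in controls were lower at 24 h than at 0 h (-0.098 to -0.169). This shift cannot give both rises and falls, but position effects differing by gene stay open. For the 158 genes changed at least 2-fold 14 of 14 second probes moved the same way, but 7 spike-ins cannot exclude such effects. With the attached times as a block, 44.4% of genes (6518) passed the F-test over the value-table times (397 with the roles exchanged), but right attachments and a right value table cannot be told apart by this, because value-table times, columns and attached replicate numbers are the same division of the arrays and replicates may differ too.

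The mean of the immediate early and MAPK feedback genes was above 0 h at each later time, with 21, 22 and 20 of 24 genes higher at 3, 6 and 24 h and EGR1 back at 0.02 at 24 h. A brief response to handling or fresh medium would have faded by 24 h, but the mean of the list was 0.73 at 24 h and 0.54 at 3 h (exact permutation p = 0.0286, two-sided, the smallest that 70 splits allow), which argues against it as the whole cause. The number of untreated arrays at 3, 6 or 24 h in the labels was 0, so treatment and time in culture cannot be told apart. A sustained response to CPP may account for the pattern, as a hypothesis that these data leave open.

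At 24 h, 17 of 25 cholesterol synthesis genes fell and 1 rose (adjusted p = 0.013 with an estimated correlation), and 16 of 34 lysosome genes rose and 2 fell (adjusted p = 0.15 with an estimated correlation, so that call was then lost). A trend with signal level is argued against for both, since the cholesterol list mean of -0.20 lay at percentile 0 of 10000 lists matched on signal (central range -0.06 to 0.11). The lysosome mean of 0.14 lay at percentile 99.97 (central range -0.05 to 0.08). Position on the slide and time in culture stay open here too, beside a response to CPP, which may account for both changes only as a hypothesis.

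ANGPTL4 (1.97 ± 0.07), G0S2 (1.70 ± 0.05) and CPT1A (1.02 ± 0.25) are known targets of PPAR nuclear receptors and rose at 24 h, CPT1A from a level well above background on 1 of 4 arrays at 0 h (0.24 after normexp correction). The hypothesis that other targets of these receptors rose with them was tested on 19 further genes and was not borne out (camera p = 0.417, mean 0.04, p = 0.638 with an estimated correlation). Of these 4 rose and 7 fell, with PLIN2 (0.57 ± 0.06), ACSL1 (0.82 ± 0.05), ACSL5 (0.51 ± 0.13) and SLC25A20 (0.18 ± 0.06) higher.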
